A study of Mus musculus with 2 samples.

How the data were processed

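H3K9me3, the trimethylation of histone H3 at lysine 9 found in constitutive heterochromatin, was mapped by ChIP-seq in mouse lung at postnatal day 0. Lungs of male and female pups of a C57BL/6N-derived stock were pooled. The labels give 1 group with 2 biological replicates, and the replicate numbers are those of the labels. Replicate 1 combined technical replicates sequenced on different instrument models, while replicate 2 had a single technical replicate, so instrument and replicate cannot be separated. Each replicate was a pool of animals, and differences between animals are not visible.

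Peaks were deposited as 4 lists on mm10 (GRCm38), per the labels: 1 list for each replicate, a pooled list called on both replicates together, and a list of replicated peaks. Control alignments were shared by both replicates, per the deposited text notes. The peak caller, its version, its filters, the aligner and the rule that made a peak replicated are not given in the sources used here. Each deposited peak carries an enrichment over the control, read here as a linear ratio or fold, a −log10 p and a −log10 q computed by the authors, a score, and the offset of its summit. The deposited score column was not used. These values belong to the peak in its own list and served only to describe, rank or filter peaks within that list. The lists hold no read counts, so the depth of each library is unknown and no value could be given a counting error. Intervals on shares of peaks are 95% Wilson intervals, which treat peaks as independent and cover counting error only. The lowest deposited −log10 p lay just above 2, which makes the lists permissive. The text therefore names the share of peaks at a q-value of 0.001 or less.

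The replicated list on the 19 autosomes, X and Y was the main peak list. Peaks on unplaced or unlocalised scaffolds were left out of all comparisons. Genes, transcripts, exons and coding sequences came from GENCODE mouse release 21 on the same build, and sequence from the GRCm38 assembly. Coordinates are 1-based. A gene had a peak when at least 1 bp of a peak lay over the gene body, and a promoter peak when it lay within 2 kb of any annotated transcription start site. Summits were assigned to promoter (within 1 kb of a start site), then exon, intron or intergenic sequence. The 13 gene lists were fixed before the data were examined, as were the tests, the named genes and the alternatives unless stated otherwise. The zinc-finger list took protein-coding symbols beginning with Zfp and a number, Zkscan or Zscan, with Zik1 and Rex2, and was not restricted to genes with a KRAB domain. The imprinted, germline, lung, liver, neural, muscle and housekeeping lists were lists of symbols. The clustered protocadherin, olfactory receptor, vomeronasal receptor and Hox lists were symbol patterns restricted to protein-coding genes.

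Observed counts were compared with 10000 circular rotations of the peaks along each chromosome, which keep the widths and spacing of peaks. The rotations do not account for where short reads can be placed uniquely. Tests were two-sided permutation tests. The smallest p that 10000 rotations can give is 0.0002, and the smallest that the 1000 rotations used for sequence composition can give is 0.002. The search over symbol stems used 100000 rotations, and its smallest p times the 261 stems is 0.00522. Benjamini-Hochberg adjustment ran over the 13 lists, the 4 features or the 4 primers. Sequence composition was the GC percentage, CpG dinucleotides per 100 bp and the percentage of soft-masked bases of the assembly. Retroviral primer binding sites were exact matches of 18 bases complementary to the 3′ end of the tRNA, on either strand, and counted when within 1 kb of a peak. Domains joined peaks at most 10 kb apart. Correlations of fold between replicates ran across overlapping peak pairs with 100000 permutations, and peaks are not independent replicates.

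Named genes were the 10 protein-coding genes with the most covered bp, the 10 with the highest fold, the genes of the 10 domains with the largest covered length, and members of the fixed lists. Lists of at most 40 genes gave up to 6 members by fold, and longer lists gave 5 by covered bp. The gene list test was tested on simulated data, in which rotated real peaks had no planted enrichment in 200 simulations per list. It called 2.5% of those simulations for the zinc-finger list of 426 genes, 1.5% for the protocadherin list of 57 and 2.5% for the imprinted list of 24. With peaks planted in 40, 19 and 8 genes of these lists it called 100% of simulations. Calls here used an unadjusted permutation p below 0.05. The simulated peaks were made by the same rotation as the test, so they do not check whether rotation is a fair comparison.

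The alternatives were the pooled list, each replicate's own list, a q-value of 0.001 or less, uniform placement of peaks, 100000 random gene lists matched on gene length, and other overlap, promoter, distance and joining rules. Rotations for the 50% overlap rule numbered 1000. Requiring overlap with a peak of each replicate, and leaving out the 25 peaks with the lowest p, were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.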

Results

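H3K9me3 was profiled in whole lung of newborn mice in 2 biological replicates, each from pooled pups, with no second tissue, age or treatment. The comparisons were therefore between replicates, and between the mark and annotated genes, sequence and chromosomes. Replicate 1 had 35387 peaks and replicate 2 had 15771. The pooled list held 9542 peaks and the replicated list 4583, of which 4422 lay on assembled chromosomes. Replicated peaks were short, with a median width of 289 bp, and covered 1.58 Mb, or 0.0596% of known bases. Their median fold over the control was 2.98, and 10.1% of them (448 peaks) had a q-value of 0.001 or less. Library depth is unknown because peak lists hold no counts.

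The replicates shared far more H3K9me3 regions than rotated peaks did, yet most peaks of either list were found in that list alone. In replicate 2, 3566 of 15578 peaks on chromosomes overlapped a peak of replicate 1 (22.9%, 95% interval 22.2 to 23.6). Rotation gave 0.772% (permutation p = 0.0002, the smallest that 10000 rotations can give). In replicate 1, 3511 of 35152 peaks overlapped a peak of replicate 2 (9.99%, 95% interval 9.68 to 10.3), against 0.343% by rotation (permutation p = 0.0002, again the smallest possible). Both replicates were compared with the same control alignments, and rotation gives no value for the overlap that a shared control alone would produce. Zinc-finger genes held 7.15% of the shared peaks of replicate 1 and 1.35% of its other peaks. In replicate 2 they held 7.94% of the shared peaks and 0.866% of the others. Fold correlated weakly across 3780 overlapping pairs, with Pearson r = 0.26 and Spearman rho = 0.189 (permutation p = 1e-05 for each, the smallest possible). Among the 174 pairs at a q-value of 0.001 or less in both replicates rho was 0.685. Both folds were ratios over the shared control, which can itself make them correlate, and the permutations do not account for it. Of the 4422 replicated peaks, 3066 (69.3%) overlapped a peak in both replicate lists and 19 overlapped neither.

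H3K9me3 peaks of the replicated list were densest on chromosomes 17 and 7 and sparse on the sex chromosomes. Chromosome 7, which carries many zinc-finger gene clusters, held 486 replicated peaks (10.99%, 95% interval 10.1 to 11.9) on 5.36% of known bases. Chromosome 17 held 324 peaks (7.33%, 95% interval 6.60 to 8.13) on 3.46% of known bases. Their densities were 3.43 and 3.53 peaks per Mb, against 1.67 over all chromosomes. Chromosome X held 51 peaks (1.15%, 95% interval 0.878 to 1.51) on 6.18% of known bases, and 3.35% of the replicated peaks at a q-value of 0.001 or less. The replicates differed there, since X held 4.54% of the peaks of replicate 1 (95% interval 4.33 to 4.76) and 0.706% of those of replicate 2 (95% interval 0.586 to 0.8503). Densities were described without a test. They do not account for sequence where short reads cannot be placed uniquely, nor for the copies of X and Y in pools of male and female pups.

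**Figure D1:**
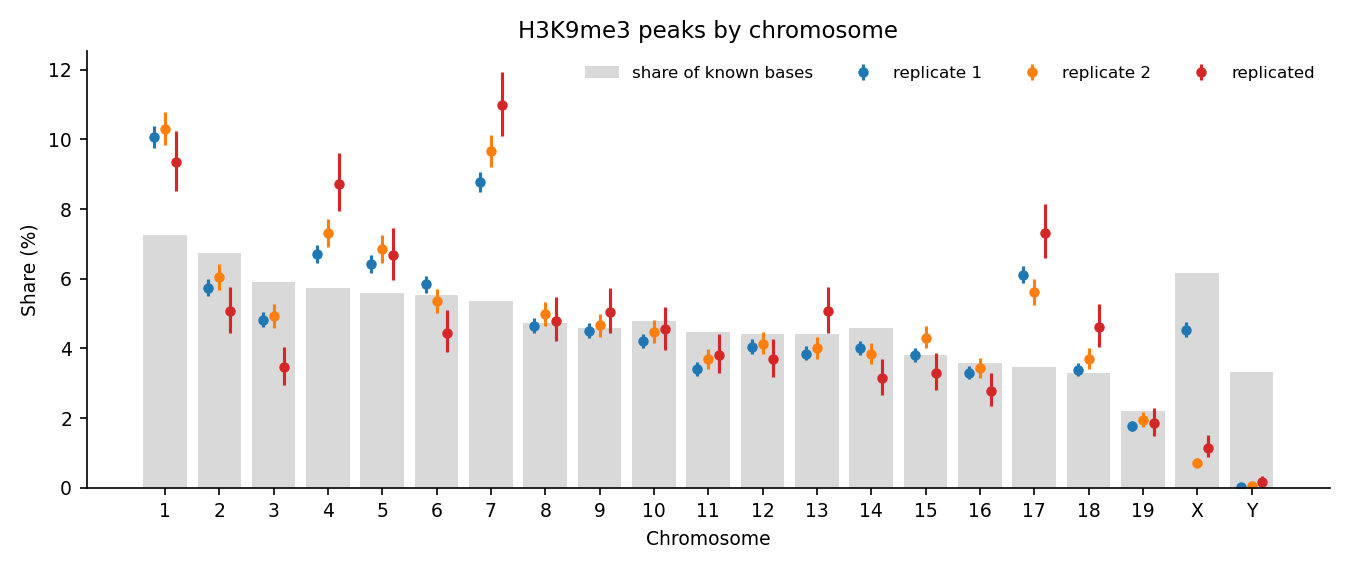
Share of H3K9me3 peaks (%) on each chromosome for replicate 1, replicate 2 and the replicated list, with 95% Wilson intervals as bars; grey columns give each chromosome's share of known bases. Chromosome 7 lies above its share of bases in all 3 lists, and on X replicate 1 stands at 4.54% and replicate 2 at 0.706%.

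Exons carried H3K9me3 summits more often than rotated peaks, and introns less often. Exons held 393 of 4422 summits, or 8.89% (95% interval 8.08 to 9.76), against 3.44% by rotation (adjusted permutation p = 0.0004). Introns held 30.3% against 40.02% (adjusted permutation p = 0.0004), and promoters held 8.30% against 6.44% (adjusted permutation p = 0.00187). Intergenic sequence held 52.6% against 50.1% (adjusted permutation p = 0.171), and passed under uniform placement (adjusted permutation p = 0.004). It exceeded rotation with the pooled list and with the lists of replicates 2 and 1, at observed over expected ratios of 1.11, 1.16 and 1.24 (adjusted permutation p = 0.000267 for each), and fell below it at a q-value of 0.001 or less, with 34.2% against 51.1% (adjusted permutation p = 0.00133). At that filter the intron call was lost, with 31.9% against 39.4% (adjusted permutation p = 0.143). The exon ratio was 2.58 with the replicated list, 1.38 with the list of replicate 2 and 1.03, no longer an excess, with that of replicate 1. The promoter excess was lost with the list of replicate 2, at 1.05 (adjusted permutation p = 0.264), and turned into a deficit of 0.846 with that of replicate 1 (adjusted permutation p = 0.000267). Sequence under replicated peaks was richer in GC (45.8% against 42.1%) and in CpG (1.16 against 0.856 per 100 bp), and poorer in soft-masked repeats (21.2% against 33.9%), each with permutation p = 0.002, the smallest that 1000 rotations can give. The CpG excess reversed with the peaks of replicate 1 alone, at 0.743 against 0.842 per 100 bp. Rotated peaks can fall in repeats where short reads cannot be placed uniquely, so the repeat deficit does not show that the mark avoids repeats.

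Zinc-finger protein genes, many of which encode DNA-binding repressors, were marked far more often than expected. A peak lay over 104 of 426 such genes, against 17.9 by rotation, a ratio of 5.81 (adjusted permutation p = 0.0013). The ratio was smaller with each replicate's own list, at 125 genes against 55.3 (2.26) for replicate 2 and 156 against 93.8 (1.66) for replicate 1, and the call held in both (adjusted permutation p = 0.0013 for each). Their promoters were marked in 28 genes against 6.04 (adjusted permutation p = 0.0013), a call that ended with either replicate's own list. Of the 106 genes with a peak over the body or promoter, 87 had the highest-fold peak matched in both replicates. Zfp873 on chromosome 10 (82048123 to 82064745, mm10) had 8108 bp under 10 peaks. Zfp981 had 6893 bp under 14 peaks, Zfp110 had 6847 bp under 11, Zfp606 had 5922 bp under 9 and Zfp180 had 5721 bp under 7. The peak with the highest fold in Zfp606, at chromosome 7, 12493086 to 12494373, lay with its summit in a coding exon. It had a fold of 5.46 in the replicated list, 4.96 in replicate 1 and 5.28 in replicate 2. Zfp90 had a coding-exon peak of fold 5.54 at chromosome 8, 106424370 to 106426127, with 6.12 in replicate 1 and 4.84 in replicate 2. Coding-exon peaks of Zfp810 and Zfp386 reached 5.09 and 4.93, and an intronic peak of Zfp958 reached 5.04.

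Imprinted loci, where 1 parental allele is silenced, were marked at most of their promoters. Of 24 genes at imprinted loci, 16 had a promoter peak against 0.443 by rotation (adjusted permutation p = 0.0013), and 15 had a peak over the body against 1.81 (adjusted permutation p = 0.0013). Ratios fell from 36.1 for promoters and 8.28 for bodies to 11.7 and 3.46 with the list of replicate 2, and to 6.59 and 2.71 with that of replicate 1, and every call held. Some of these genes share a promoter peak, as Peg10 and Sgce do, and the rotation keeps that sharing. Mest had a fold of 4.32 at chromosome 6, 30737632 to 30738430, with its summit in a non-coding exon or UTR 210 bp from a start site. The fold was 4.52 in replicate 1 and 4.55 in replicate 2. Grb10, an inhibitor of growth factor receptor signalling, had a fold of 3.83 at chromosome 11, 12026391 to 12027121, 70 bp from a start site. Nnat had a fold of 3.71 at chromosome 2, 157558488 to 157558869, upstream of the gene. Meg3, a long non-coding RNA, had a fold of 3.59 at chromosome 12, 109538652 to 109539453, 2183 bp from the nearest start site and outside the gene. The peak of Peg10 on chromosome 6, at 4747599 to 4747894, lay with its summit in an intron 370 bp from a start site, and 569 bp from a start site of Sgce. It had a fold of 3.47, with 2.93 in replicate 1 and 3.5998 in replicate 2. At a q-value of 0.001 or less only 2 imprinted genes kept a peak. The body call was lost with this count (adjusted permutation p = 0.104), although the ratio rose to 11.7, and the promoter call held (adjusted permutation p = 0.0182).

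Germline genes, silent in most somatic tissues, were marked in 6 of 30 cases against 1.16 by rotation (adjusted permutation p = 0.0026). They were Dazl, Ddx4, Mael, Piwil1, Tdrd1 and Tdrd9. Dazl, Ddx4 and Mael carried the peak at the promoter, which exceeded the 0.282 expected (adjusted permutation p = 0.0169). This promoter ratio of 10.6 was 5.55 with the list of replicate 2 and 3.99 with that of replicate 1, and the call held. The summit in Ddx4, an RNA helicase of germ cells, lay in an intron 193 bp from a start site at chromosome 13, 112651723 to 112652341. Its fold was 3.34, with 3.46 in replicate 1 and 3.79 in replicate 2. The Mael peak had a fold of 3.10 and lay in a coding exon 186 bp from a start site. The Piwil1 peak was intronic, with a fold of 2.86, and overlapped no peak of either replicate's own list. No germline gene had a peak at a q-value of 0.001 or less, and the body call was lost with replicate 2 alone (adjusted permutation p = 0.632, ratio 1.44, against 1.69 with replicate 1 alone) and under uniform placement (adjusted permutation p = 0.0519).

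Clustered protocadherins, cell adhesion proteins encoded in tandem arrays, had peaks within 2 kb of a start site more often than expected. A promoter peak lay at 26 of 57 genes against 0.426 by rotation, a ratio of 61.0 (adjusted permutation p = 0.00173). The ratio was 24.96 with the list of replicate 2 and 14.6 with that of replicate 1, and the call held. Most of the genes with a promoter peak in the replicated list are gamma genes inside 1 domain of 68 peaks on chromosome 18. Their start sites lie close together, so these promoters are not separate loci. Broad coverage of the gamma cluster was not told apart from marking of promoters. Over gene bodies the count was 29 against 5.22 and did not pass adjustment (adjusted permutation p = 0.153). Bodies did pass with the pooled list (41 against 9.52, adjusted permutation p = 0.0199), with the list of replicate 2 (43 against 16.4, adjusted permutation p = 0.00867), with that of replicate 1 (46 against 23.6, adjusted permutation p = 0.0136) and against lists matched on gene length (4.29 expected, adjusted permutation p = 8.67e-05). The genes of the gamma cluster are nested, and the middle 95% of rotations reached 28 genes. Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1 and Pcdhga4 had between 31903 and 35268 bp under peaks, which they share. Olfactory receptor genes had a peak in 12 of 1135 cases against 12.8 (adjusted permutation p = 1), among them Olfr131 with a fold of 3.10 and Olfr1451 with a fold of 3.10. With the peaks of replicate 1 alone the count was 150 against 86.6 (adjusted permutation p = 0.0229). Vomeronasal receptor genes had a peak in 20 of 329 cases against 10.1 (adjusted permutation p = 0.178), among them Vmn2r93 with 4 peaks and Vmn2r60 with 3. They passed with the pooled list, at 37 genes against 19.2 (adjusted permutation p = 0.0437), with the list of replicate 1, at 88 against 53.7 (adjusted permutation p = 0.0121), and against lists matched on gene length, with 7.38 expected (adjusted permutation p = 0.000585), but not with the list of replicate 2, at 48 against 30.8 (adjusted permutation p = 0.133).

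No gene of the lung epithelium list or of the lung mesenchyme, endothelium and immune list had a replicated peak over its body or promoter, in 25 genes each. Rotation gave 0.765 and 1.27 genes, so these lists were too small to show depletion (adjusted permutation p = 1 for each). No Hox gene of 39 and no housekeeping gene of 20 had a peak, against 0.43 and 0.470 expected (adjusted permutation p = 1 for each). Among liver genes only Cyp3a11 had a peak, among muscle genes only Ttn, and among neural genes Slc17a7 and Syt1. None of these lists passed the test (adjusted permutation p = 1 for each). With the peaks of replicate 1 alone, the lung mesenchyme, endothelium and immune list had 2 marked genes against 7.04 (adjusted permutation p = 0.0472), and the neural list had 10 against 6.001 (adjusted permutation p = 0.0472). Ttn, the giant sarcomere protein, had 11 peaks covering 3963 bp, the highest with a fold of 3.59 in a coding exon. Slc17a7, a vesicular glutamate transporter, had a fold of 3.37 in a non-coding exon or UTR 73 bp from a start site. Cyp3a11 had a fold of 2.86 and no overlapping peak in replicate 1.

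**Figure D2:**
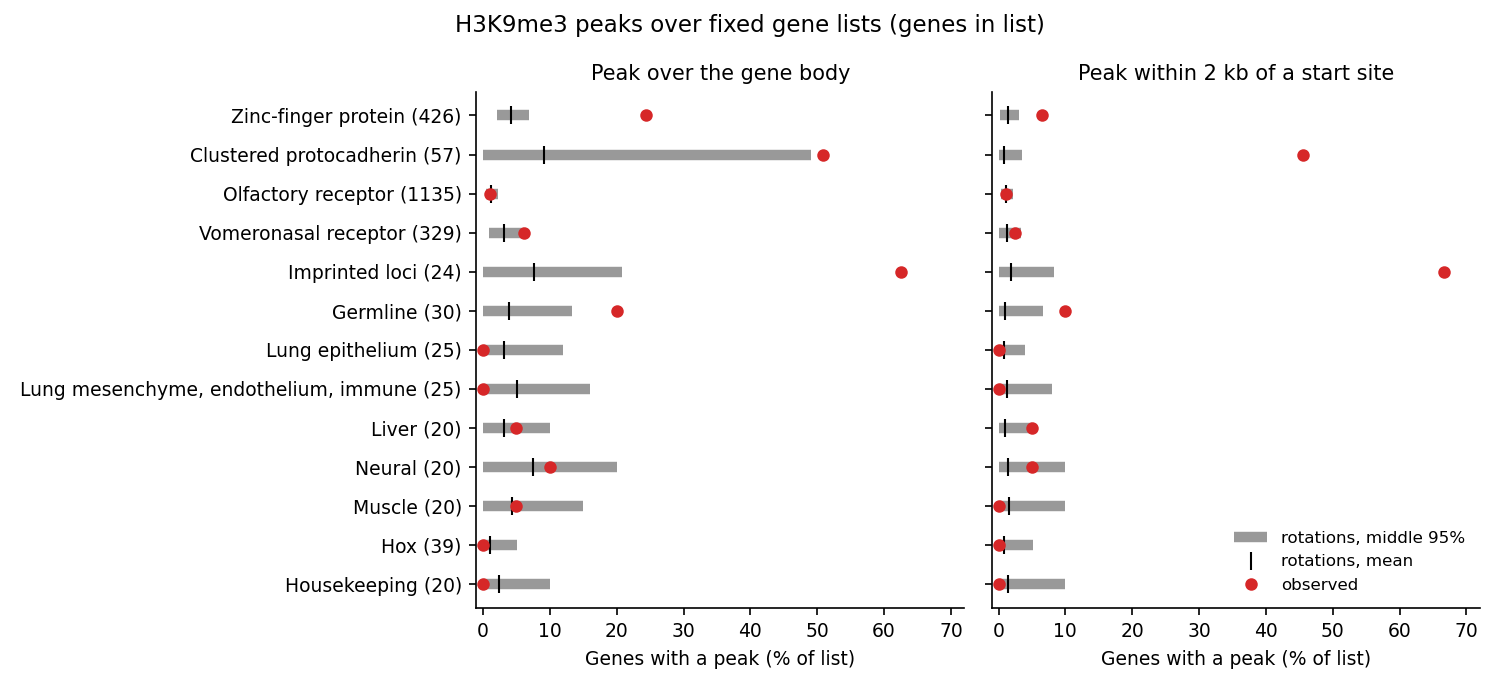
Percent of the genes of each fixed list with a replicated H3K9me3 peak over the gene body (left) or within 2 kb of a start site (right); numbers in brackets are genes per list, red points are observed values, black ticks the mean of 10000 rotations and grey bars their middle 95%. Zinc-finger genes (24.4%), protocadherins (50.9%), imprinted loci (62.5%) and germline genes (20%) lie above the grey bars on the left, where protocadherins did not pass adjustment. The same 4 lists do so on the right, at 6.57%, 45.6%, 66.7% and 10%.

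Peaks gathered into 183 domains of 3 or more peaks, which held 1090 replicated peaks (24.6%). The number of such domains was 443 with the pooled list, 577 with the list of replicate 2, 2150 with that of replicate 1 and 31 at a q-value of 0.001 or less. The domain with the most covered sequence spanned the gamma protocadherins on chromosome 18, with 68 peaks covering 35774 bp. The next, on chromosome 1 from 88211604 to 88256797 (mm10), had 35 peaks covering 33135 bp over the 3′ part of the Ugt1a genes, which encode glucuronidating enzymes, and over Mroh2a. It took in the start site of Ugt1a1, which had 6092 of its 7039 bp under peaks. Peaks of replicate 1 covered 29175 bp of it and peaks of replicate 2 covered 30560 bp. A neighbouring domain from 88281829 to 88310814 had 22 peaks over Trpm8, a cold-sensing ion channel, covering 12131 bp. Other domains covered 9999 bp at Smok2a and Smok2b, 9423 bp at Plec, 9318 bp at Zfp873, 9051 bp at Zfp146 and 7930 bp at 2610008E11Rik. A domain on chromosome 11 from 3184220 to 3200099 covered 14088 bp at Sfi1 and Drg1. A further domain on chromosome 4, from 121998473 to 122044441, covered 13234 bp and held no protein-coding gene. Covered length did not follow fold. The median fold was 2.28 in the Ugt1a and Mroh2a domain, 2.19 in the Trpm8 domain and 2.14 in the Sfi1 and Drg1 domain. It was 2.73 or more in the other domains named. A large covered length at a low fold does not show strong enrichment, and a high local background was not excluded there. Domains were described without a test.

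**Figure D3:**
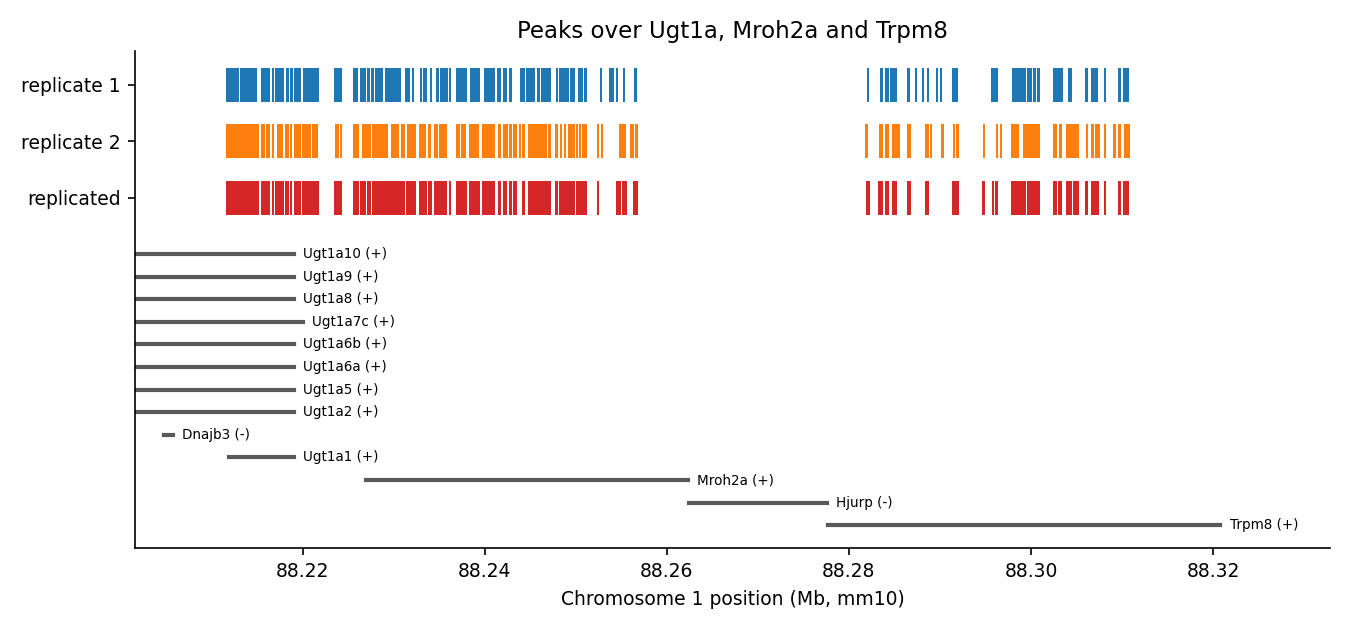
Peaks of replicate 1, replicate 2 and the replicated list (coloured boxes, to scale) over protein-coding genes (grey lines with strand, cut at the window edges) along chromosome 1 in Mb of mm10. The window holds 70 peaks of replicate 1, 75 of replicate 2 and 57 replicated peaks, and none lies over Hjurp. The median fold of replicated peaks was 2.28 in the Ugt1a and Mroh2a domain and 2.19 in the Trpm8 domain.

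Outside the zinc-finger list, which was drawn from gene symbols, the highest folds over protein-coding genes were at Klf14, Gm21887, Mfhas1, Asmt and Plec. Klf14, a single-exon gene for a Krüppel-like transcription factor that also carries zinc fingers, had the highest, with a fold of 7.53 at chromosome 6, 30956892 to 30958787, in a coding exon. It was 7.72 in replicate 1 and 5.67 in replicate 2. Gm21887 on X had a fold of 6.08, with 6.77 in replicate 1 and 4.18 in replicate 2. Mfhas1 had an intronic peak of fold 5.27, with 7.18 in replicate 1 and 4.70 in replicate 2. Asmt, the last enzyme of melatonin synthesis, and Plec, a cytoskeletal linker, each reached 5.05.

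Primer binding sites, which mark the 5′ ends of retroviral insertions, lay near peaks more often than expected for 3 of 4 tRNAs. For the proline tRNA, 17 of 174 sites lay within 1 kb of a replicated peak (9.77%, 95% interval 6.19 to 15.1), against 0.482 by rotation (adjusted permutation p = 0.0004). For the Lys1,2 tRNA it was 7 of 67 sites against 0.252 (adjusted permutation p = 0.0004). For the phenylalanine tRNA it was 14 of 1090 against 3.82 (adjusted permutation p = 0.000533). For the Lys3 tRNA it was 1 of 62 against 0.214 (adjusted permutation p = 0.389), and with the list of replicate 1 it was 9 against 1.68 (adjusted permutation p = 0.0002, the smallest possible). The lists of replicates 2 and 1 gave ratios of 12.03 and 9.84 for proline sites, against 35.2 with the replicated list, and 10.5 and 6.83 for Lys1,2 sites, against 27.8. At a q-value of 0.001 or less only the proline sites passed, with 9 sites against 0.0579. When a site had to lie inside a peak, again only proline sites passed, with 3 against 0.0854 (adjusted permutation p = 0.0008). No Lys1,2, Lys3 or phenylalanine site lay inside a peak, against 0.0456, 0.0378 and 0.688 expected, too few to show a deficit.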

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

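The replicated list also held 161 peaks on 15 unplaced or unlocalised scaffolds, which entered no comparison above. They stood out because they are signal outside the analysed chromosomes. They covered 98323 bp, and their median −log10 p was 8.63, against 4.88 for the chromosomal peaks. Their median fold was 2.90, against 2.98. No explanation was tested for them.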

How the results depend on the processing

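Of 297 recomputed values, 223 stayed the same. Among these, tested values kept their direction and their side of the threshold, and untested values stayed close. Another 14 moved from below to past the threshold, 9 moved back below it, 37 turned the other way and 14 untested values moved. Some of the 37 were counts of 0 where rotation expected under 1, as for Lys1,2 sites at a q-value of 0.001 or less (0 against 0.0264). Such a 0 does not show a change of direction. The cause was not tested for any of these changes, except that a stricter filter leaves fewer peaks by construction. Overlap between replicates, their fold correlation, the zinc-finger gene bodies, the imprinted promoters, the protocadherin promoters and the proline primer sites stayed past the threshold under every alternative run. Their ratios with a single replicate's list were lower, at 1.66 to 2.26 for zinc-finger bodies, 6.59 to 11.7 for imprinted promoters, 14.6 to 24.96 for protocadherin promoters and 9.84 to 12.03 for proline sites. Peaks had no counts, so the effect of depth could not be measured. Every alternative for overlap and fold correlation kept the shared control, so agreement beyond that control was not measured either. Overlap with a peak of each replicate, and leaving out the 25 peaks with the lowest p, were chosen after the data were seen.

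At a q-value of 0.001 or less, 1176, 354, 466 and 448 peaks remained in the replicate 1, replicate 2, pooled and replicated lists, chromosome X held 3.35% and chromosome 7 held 8.26% of replicated peaks, and 31 domains remained. Observed over expected was then 0.669 for intergenic sequence, 0.811 for introns, whose call ended, 11.7 for imprinted gene bodies and 2.36 for phenylalanine primer sites. It was 0 for vomeronasal promoters, for germline, liver and neural bodies and promoters, for muscle bodies and for Lys1,2 and Lys3 primer sites. Rotation expected at most 0.388 genes or sites in each of these, so a count of 0 shows no deficit. The ratio was also 0 for the Lys1,2, Lys3 and phenylalanine sites when a site had to lie inside a peak, and for liver bodies and promoters when peaks had to overlap each replicate. At most 0.688 were expected there.

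With the pooled list the ratio was 1.11 for intergenic sequence, 4.31 for protocadherin bodies, 1.53 and 1.56 for olfactory bodies and promoters, 1.93 for vomeronasal bodies, 0.813 for liver and 0.772 for neural bodies, and domains numbered 443. Uniform placement gave 1.05 for intergenic sequence, which then passed, 4.26 for germline, 0.954 for neural and 0.825 for muscle bodies. Random lists matched on gene length gave 6.75 for protocadherin and 2.71 for vomeronasal bodies.

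With either replicate left out, so that the other replicate's own list was used, values ranged over 0.706 to 4.54% of peaks on chromosome X, 8.77 to 9.65% of peaks on chromosome 7 and 577 to 2150 domains of 3 or more peaks. Observed over expected ranged over 1.16 to 1.24 for intergenic summits, 1.03 to 1.38 for exons, 0.846 to 1.05 for promoters, 0.882 to 1.18 for CpG per 100 bp, 1.95 to 2.63 for protocadherin bodies, 1.47 to 1.73 for olfactory bodies, 1.56 to 1.64 for vomeronasal bodies, 1.44 to 1.69 for germline bodies, 0.284 to 0.951 for lung mesenchyme, endothelium and immune bodies, 0.264 to 0.457 for liver bodies, 1.497 to 1.67 for neural bodies, 0.385 to 0.481 for muscle bodies, 1.17 to 1.56 for Hox bodies and 2.80 to 5.37 for Lys3 sites. Over promoters of the lists it ranged over 1.09 to 1.56 for zinc-finger promoters, 1.59 to 1.90 for olfactory promoters, 0 to 2.45 for lung epithelium promoters, 0.704 to 1.41 for liver promoters and 0.783 to 1.54 for Hox promoters.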

Other observations

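The pooled list was shorter than either replicate's own list, with 9542 peaks against 35387 and 15771. Of the 51 replicated peaks on X, 17 lay in the 1 Mb bin that begins at 31 Mb, and 9 and 8 lay in the bins at 169 and 170 Mb, which hold Gm21887, Mid1 and Asmt. Each of these 3 bins held 5 peaks at a q-value of 0.001 or less, and no other bin of X held any. They were picked after their values were seen.

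The following tests were set before the result each measures was seen, except that the counts by locus and without an added count, and the pooled list, used for the lowest p-values, were chosen after, as were the 100000 rotations of the family search. The word test replaced a test on olfactory genes whose value had been seen, and the implied background was recomputed, after its first value had been seen, to correct the calculation. Zinc-finger genes stood out in number, and 3 explanations were weighed. Reads shared between paralogs would leave few unique words under the peaks. Of the 31-base words of the 314 peaks over zinc-finger genes, however, 96.7% occurred once in the assembled chromosomes (95% interval 95.9 to 97.4). This was close to the 96.5% of other replicated peaks. The words speak only to copies in the assembled chromosomes, not to copies missing from them, and the filters applied to reads are unknown. Weak peaks near the calling threshold are argued against as the only source. At a q-value of 0.001 or less, 42 zinc-finger genes still had a peak over the body against 1.71 by rotation, a ratio of 24.6. The whole replicated list gave 104 such genes, so many of the marked genes rest on weaker peaks. A candidate explanation is that the mark lies over the last coding exon, taken here to encode the zinc-finger array. In that exon lay 111 of 312 summits (35.6%), 4.52 times the number from rotation within genes (permutation p = 0.0002, the smallest possible). This places the mark within genes that already had a peak, and does not show why these genes were marked. Whether this placement is specific to lung was not tested, since no other tissue was analysed here.

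Chromosome X held 4.54% of the peaks of replicate 1 and 0.706% of those of replicate 2. The length of the replicate 1 list by itself is argued against, because its 15578 peaks with the lowest p still had 3.86% on X (95% interval 3.57 to 4.17). At a q-value of 0.001 or less, however, X held 2.30% of peaks in replicate 1 (95% interval 1.58 to 3.32) and 3.39% in replicate 2 (95% interval 1.95 to 5.83). The higher share in replicate 1 was thus not seen among the strongest peaks, which on X were only 27 in replicate 1 and 12 in replicate 2. In the replicated list, every X peak at that filter lay in the bins that begin at 31, 169 and 170 Mb. The shares at that filter therefore need not describe X as a whole. Equal numbers of peaks need not be equally strict, so a part played by weaker peaks stays open. The 10 fullest 1 Mb bins held 24.6% of the X peaks of replicate 1, just under the 25% set beforehand as arguing against a few loci. These peaks lay in 149 bins, so a few loci did not hold most of them. A smaller part played by a few loci is not excluded. A different male to female makeup of the pools stays open: Y held 0.0199% of peaks in replicate 1 and 0.0385% in replicate 2, with intervals that overlap, from 7 and 6 peaks.

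The 25 replicated peaks with the lowest p, which are also the 25 lowest-p peaks of the longer pooled list, had a median fold of 3.23, and among them were 7 at Sfi1 and Drg1 on chromosome 11 with folds of 2.07 to 2.55. Disagreement between replicates is argued against, since 92% of the 25 overlapped a peak of each replicate (95% interval 75.03 to 97.8), against 34.7% of all pooled and 69.3% of all replicated peaks. A high local background, as at sequences with more copies in the genome than in the assembly, cannot be told apart from other sources. Under an assumed Poisson model, 52% of the 25 had an implied background of at least 5 times the median of all replicated peaks. That is 13 peaks, just past the criterion of over 50%, and the share was 44% without an added count of 1 and 33.3% (6 of 18) when peaks within 10 kb were counted as 1 locus. Over all 4422 replicated peaks the share at 5 times the median or more was 1.02% (45 peaks). The implied background is computed from the same fold and p that made the 25 stand out, so it cannot say what raised the counts there.

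A search for other gene families used 261 symbol stems with at least 10 protein-coding members outside the fixed lists. With 100000 rotations 0 stems passed at an adjusted permutation p below 0.05, and 3 were higher at an unadjusted permutation p below 0.05 (Ceacam, Skint and Ugt). The lowest was Ceacam, with 6 of 15 genes against 0.507 (adjusted permutation p = 0.219). A family of this size with a ratio of 11.8 did not pass, so enrichment of other families is not excluded.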
